A study of Homo sapiens with 9 samples.

How the data were processed

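Poly(A) RNA from 9 samples of the NCI-H358 line was measured by RNA sequencing, 3 each of parental cells, resistant cells off drug and resistant cells on drug. Per the labels' protocols, cells were grown in medium with 10% serum, mRNA was enriched with oligo(dT) beads, and libraries were made with the NEBNext Ultra II RNA kit and sequenced on an Illumina NovaSeq as pairs of 150-base reads. Per the submitters' processing notes, bcl2fastq 2.17, FastQC 0.12.1, Salmon 0.14.1 and the build GRCh38.p13 were used, with no role or order stated. The annotation release, the strand setting and the tool that summed transcripts to genes are not given in the sources used here.

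The authors deposited a table of estimated counts per gene, which are not whole numbers and are not scaled for depth, and a table of TPM values, which are scaled for transcript length and depth. The design had been fixed on the assumption of plain counts. The estimated counts were therefore rounded to whole numbers before any count test. The tables hold 60230 genes, of which 60089 have a symbol in the symbol table used here. The other 141 were kept by identifier and held at most 0.028% of a library's counts. Gene positions are from GENCODE release 29 on GRCh38 and were matched by gene identifier for 17082 of the 17307 genes tested (98.7%).

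Fold changes were estimated with edgeR 4.0.16 in R 4.3.3 from 1 fit of all 9 libraries, with a mean per group and no covariate, TMM scaling, and filterByExpr on the group (minimum count 10, minimum total 15). The quasi-likelihood test had 6 residual degrees of freedom, and the common biological coefficient of variation was 0.0946. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The lists, 42 in number, were tested against the other genes with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists. Beside it stand camera with a correlation estimated per list and fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Adjustment over the list alone gave the same numbers of members in 103 of 126 list results and differed by at most 3 members in the other 23.

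The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. Per comparison the rule took the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 2 and no overlap between groups, leaving out antisense, readthrough, pseudogene, clone-based, LOC and LINC names. It added up to 4 called members per list with an average log2 CPM of at least 1, or the member with the highest level where fewer than 2 passed, and in every comparison HRAS, NRAS, EGFR, MET, AXL, DUSP6, SPRY4, ETV4, CCND1, CDH1, VIM, ZEB1 and MKI67. The text names a selection of these genes, and some genes that the rule took are not reported here.

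The steps were tested on simulated counts drawn from the real means and library sizes. Per comparison, 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold. All other genes were unchanged, so scaling where many genes change was not tested. Between off-drug and parental cells (16746 genes), 56.7, 92.5 and 98.5% of genes changed 1.5-, 2- and 4-fold were recovered, and 4.6% of calls were false. Between on-drug and parental cells (16792 genes), 65.7, 88.1 and 100% were recovered with 8.6% false calls, and between on-drug and off-drug cells (16770 genes) 68.7, 89.6 and 98.5% with 6.6%. In a simulation with 1 shifted list, camera called it and 0 of the 41 others. Genes were drawn independently there, so this does not test the preset correlation.

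Replicates were checked for a library deposited more than once. The lowest chi-square per degree of freedom within a group was 5.114, so no pair agreed within sampling noise and none was merged. This does not show that the libraries came from separate cultures. Alternatives were RLE and upper-quartile factors and library size only, no filter and a stricter filter, DESeq2 1.42.0, limma voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a replicate block, fits of only the groups compared, and each library left out. The lists called without off-drug replicate 2 were added after the data were seen. The reads themselves and any DNA measurement were not used here.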

Results

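RNA sequencing of poly(A) RNA was used to compare 3 states of NCI-H358, an established human lung cancer cell line. The series concerns how these cells acquire resistance to sotorasib, a targeted cancer drug. Parental cells were sensitive to the drug and untreated. The resistant derivative, NCI-H358-R, had been selected in 250 nM sotorasib for about 2 months. It was profiled without the drug (off drug) and 4 days after dosing with 250 nM (on drug). How long the off-drug cells had been without sotorasib is not given in the sources used here. Each state had 3 libraries, described as biological replicates. The labels do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

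Total counts, in units of 1e6, were 25.7 to 31.79 in parental libraries, 25.73 to 33.99 off drug and 33.39 to 34.73 on drug. In a single library, 3 counts correspond to 0.0776 to 0.123 CPM (counts per 1e6 counts), and such floors cover counting error only. The on-drug libraries stood apart in makeup. They held counts for 24189 to 24360 genes, against 22079 to 22957 in the other libraries, and their TMM scaling factors were 1.113 to 1.124, against 0.917 to 0.972. Mitochondrially encoded genes took 3.88 to 5.29% of counts in parental libraries, 2.93 to 3.45% off drug and 4.01 to 5.04% on drug. Across genes, log CPM values correlated at r = 0.986 to 0.991 between libraries of one state and at 0.904 to 0.951 between states. The first principal component held 55.3% of the variance and parted the on-drug libraries from the others. The second held 29.1% and parted off-drug from parental libraries. Levels below are means ± SD in TMM-scaled CPM over 3 libraries per state, and changes are log2 fold changes ± SE with Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test. Counts of list members are over all genes tested. Adjusted over the list alone they were the same, except where a second count is given.

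**Figure D1:**
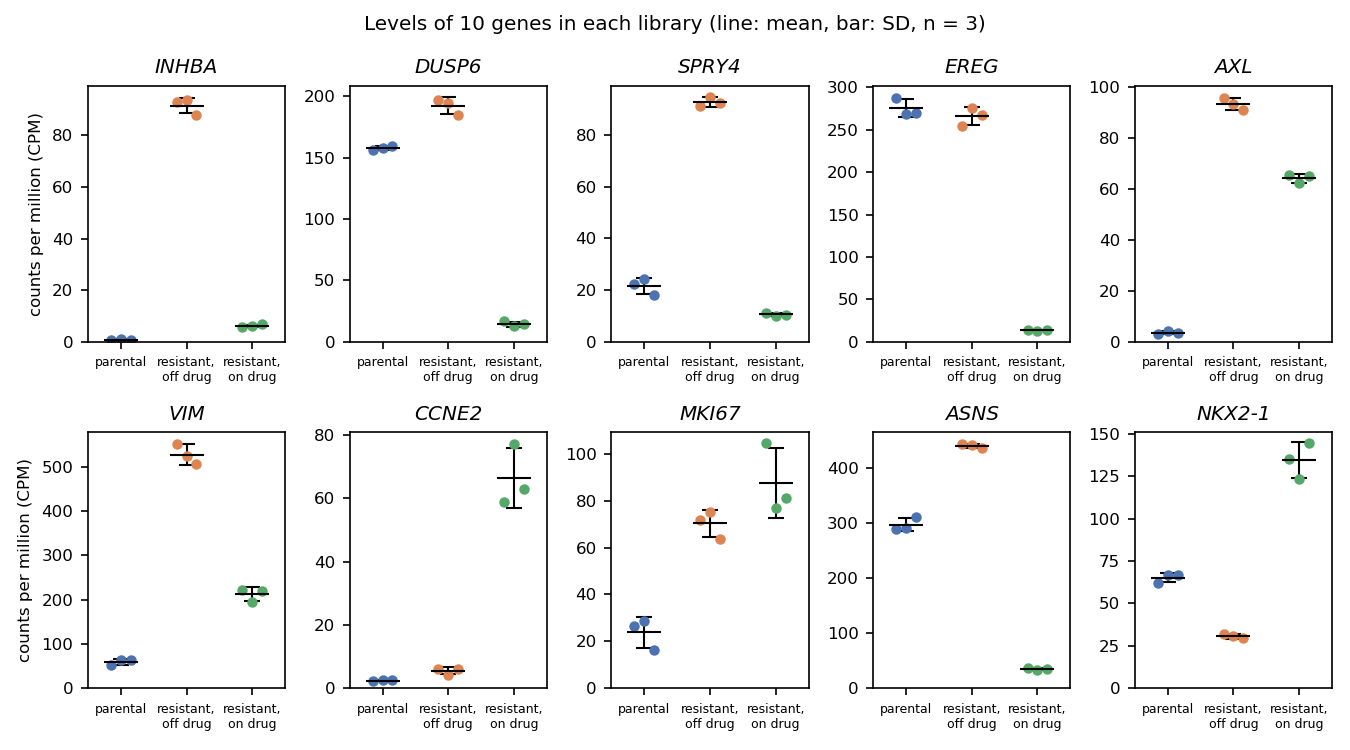
CPM of 10 genes (vertical axes, each starting at 0) in the 3 libraries of each state (points), with the mean (line) and SD (bar), n = 3. INHBA, AXL and VIM lay above the parental libraries in both resistant states, and DUSP6, EREG and ASNS were lowest on drug.

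The first comparison asked what distinguished resistant cells from the parental line when no drug was present. NCI-H358-R was the only resistant derivative, so differences tied to resistance cannot be told apart from other differences between it and the parental line. The time off drug is not given, so an effect of withdrawal cannot be told apart here either. Off-drug resistant cells carried more transcripts of mesenchymal, TGF-beta response, YAP/TEAD target, ERK output and cell cycle genes, and fewer of squamous, epithelial and NRF2 target genes. These list calls rest on a preset correlation between genes, and with an estimated correlation none of them was called (adjusted p = 0.056 to 0.31). VIM, an intermediate filament gene of mesenchymal cells (ENSG00000026025.16, chromosome 10, 17228259 to 17237593), rose from 60.2 ± 6.69 to 527 ± 23 CPM, a change of 3.13 ± 0.10 (adjusted p = 2.5e-12). AXL, a receptor tyrosine kinase (ENSG00000167601.12, chromosome 19, 41219203 to 41261766), rose from 3.54 ± 0.563 to 93.4 ± 2.33 CPM (4.73 ± 0.11, adjusted p = 6.8e-14). TP63, a transcription factor of squamous and basal epithelium, fell from 46.7 ± 6.58 to 4.18 ± 1.32 CPM (−3.49 ± 0.16, adjusted p = 1.5e-10). In all, 4913 of 17307 genes were higher and 4602 lower, of which 1297 and 1684 changed at least 2-fold.

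Between off-drug and parental cells HRAS, a RAS family gene, fell (−0.52 ± 0.10, adjusted p = 0.00032), and NRAS was measured at 155 ± 5 and 154 ± 8.16 CPM (−0.01 ± 0.09, adjusted p = 0.91). Of 24 members and regulators of the RAS-RAF-MEK-ERK cascade, 13 rose and 4 fell (14 and 5 adjusted over the list alone), including a rise of RASA1, a RAS GTPase-activating protein (1.30 ± 0.09). As a list they were not called (adjusted p = 0.057), though they were with the replicate block (adjusted p = 0.043). Among 25 receptor tyrosine kinases, 9 rose and 10 fell and the list was not called (adjusted p = 0.18). Its median of −0.15 and mean of 0.78 differed in sign. EGFR (1.37 ± 0.13) and MET (0.64 ± 0.11) rose and FGFR3 fell (−1.74 ± 0.15).

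Transcripts read as output of ERK signalling rose in off-drug cells: 17 of 22 rose and 2 fell, with a median of 0.72 (camera adjusted p = 3.2e-10, and adjusted p = 0.17 with an estimated correlation). FOSL1, an AP-1 subunit, rose 3.10 ± 0.09, and SPRY4, a feedback inhibitor of receptor signalling, 2.10 ± 0.10. MYC rose 1.37 ± 0.08 and the cyclin gene CCND1 1.16 ± 0.09. ETV4 rose 0.50 ± 0.08. DUSP6, an ERK phosphatase (ENSG00000139318.8, chromosome 12, 89347232 to 89353271), went from 158 ± 1.7 to 192 ± 6.78 CPM (0.28 ± 0.09, adjusted p = 0.013). That call was lost without off-drug replicate 1 (0.27, adjusted p = 0.053) and without off-drug replicate 2 (0.26, adjusted p = 0.053).

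Among 23 mesenchymal genes, 16 rose and 3 fell, with a median of 1.27 (adjusted p = 4.2e-14, and adjusted p = 0.057 with an estimated correlation). SPARC, a matrix glycoprotein (ENSG00000113140.11, chromosome 5, 151661096 to 151687165), rose from 2.47 ± 0.0397 to 189 ± 14.2 CPM (6.25 ± 0.11), and ZEB1, a repressor of epithelial genes, rose 3.16 ± 0.18. Of 9 tested fibroblast markers, 4 rose and 1 fell, with a median of 1.20, and the list was not called (adjusted p = 0.5). Of 20 YAP/TEAD targets, 18 rose and 0 fell, with a median of 1.04 (adjusted p = 2.7e-21, and adjusted p = 0.056 with an estimated correlation). They included CCN1 (3.04 ± 0.09) and CCN2 (3.06 ± 0.11), which encode matricellular proteins. Of 19 TGF-beta response genes, 13 rose and 5 fell (adjusted p = 1.3e-09, and adjusted p = 0.056 with an estimated correlation). INHBA, a subunit of activin (ENSG00000122641.11, chromosome 7, 41667168 to 41705834), rose from 0.761 ± 0.176 to 91.4 ± 2.97 CPM (6.92 ± 0.13), whereas the integrin gene ITGB6 fell (−1.99 ± 0.10). Of 25 integrin and laminin genes, 15 rose and 7 fell (adjusted p = 0.023, and adjusted p = 0.73 with an estimated correlation), a call lost without off-drug replicate 2 (adjusted p = 0.06). Of 24 NF-kB and inflammatory genes, 14 rose and 4 fell (adjusted p = 0.0025, and adjusted p = 0.17 with an estimated correlation), with TNFAIP3 up 3.82 ± 0.16.

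Cell cycle genes rose as well. Of 30 replication and G1/S genes, 25 rose and 0 fell (adjusted p = 2.6e-13, and adjusted p = 0.056 with an estimated correlation), and of 30 mitotic genes 27 rose and 0 fell (adjusted p = 3.4e-13, and adjusted p = 0.056 with an estimated correlation). MCM10, a replication initiation factor, rose 1.83 ± 0.11 and the proliferation marker MKI67 rose 1.56 ± 0.17. Of 9 tested replication-dependent histone genes, 7 rose (adjusted p = 0.04, and adjusted p = 0.3 with an estimated correlation). These mRNAs mostly lack poly(A), on which the libraries were selected. Of 17 immediate early and heat shock genes, 9 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.019, and adjusted p = 0.46 with an estimated correlation), EGR1 among them (from 11.7 ± 1.57 to 66.3 ± 3.95 CPM).

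Among the lists that fell, 10 of 13 squamous and basal genes were lower and 0 higher (adjusted p = 3.4e-07, and adjusted p = 0.063 with an estimated correlation). Of 24 NRF2 targets, 14 fell and 1 rose (adjusted p = 7.3e-07, and adjusted p = 0.056 with an estimated correlation). NQO1, a quinone reductase, fell −1.08 ± 0.08. Of 27 epithelial genes, 17 fell and 1 rose (adjusted p = 1.6e-05, and adjusted p = 0.31 with an estimated correlation). CLDN3, a tight junction gene, fell −2.03 ± 0.12, while the E-cadherin gene CDH1 was measured at 259 ± 4.86 and 223 ± 17 CPM (−0.21 ± 0.10, adjusted p = 0.091). Of 22 antigen presentation genes, 11 fell and 3 rose (adjusted p = 0.023, and adjusted p = 0.3 with an estimated correlation), with B2M at −1.20 ± 0.11 and CD274 up 1.41 ± 0.11. Airway secretory genes fell in 7 of 18 cases and rose in 3 (adjusted p = 0.0024, and adjusted p = 0.29 with an estimated correlation), and lysosomal genes fell in 16 of 26 and rose in 3 (adjusted p = 0.02, and adjusted p = 0.29 with an estimated correlation). Of 29 nuclear respiratory chain genes, 21 fell and 1 rose (2 rose adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.73 with an estimated correlation), a call lost without off-drug replicate 2 (adjusted p = 0.054). Of 13 mitochondrially encoded genes, 8 fell and 0 rose (adjusted p = 0.032, and adjusted p = 0.73 with an estimated correlation).

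The 8 largest rises under the naming rule included BPIFB4, at 0.0882 ± 0.0482 CPM in parental cells and 15.1 ± 1.15 off drug (7.40 ± 0.21), and the endothelial receptor gene TIE1 (6.06 ± 0.23). Markers of other cell types moved too. Of 6 tested endothelial markers 4 rose and 0 fell (adjusted p = 0.0051, and adjusted p = 0.24 with an estimated correlation), led by ESAM at 16.2 ± 0.602 CPM off drug against 1.01 ± 0.222. Of 5 tested leukocyte markers 3 rose and 1 fell, and the list was not called (adjusted p = 0.2). The largest falls included CP, the gene for ceruloplasmin (−5.93 ± 0.42), CAPS (−5.49 ± 0.34) and GPX2, a glutathione peroxidase (−5.83 ± 0.27). SPANXA2 (−5.77 ± 0.45) shares reads with near-identical copies, so its value is uncertain. Off-drug replicate 2 decided the size of these 4: without it the changes were −8.54 for CP, −6.48 for CAPS, −6.56 for GPX2 and −7.39 for SPANXA2. Without off-drug replicate 3 that of CP was −5.29. In off-drug replicate 2 CP, CAPS and SPANXA2 stood at 4.72, 4.58 and 4.54% of the parental mean, against at most 1.21% in the other off-drug libraries.

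Of the 42 lists, 19 were called, 11 higher and 8 lower. With an estimated correlation camera called 0 (9 at an unadjusted p under 0.05) and fry called 33. Among lists not called, 13 of 22 p53 targets fell and 4 rose (adjusted p = 0.062). They were called with upper-quartile factors (adjusted p = 0.049) and with the replicate block (adjusted p = 0.04). Also not called were the 23 ATF4 response genes, of which 11 rose and 4 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.39). On log2(TPM + 1) values for genes with a mean TPM of at least 1, 4609 genes were higher and 2529 lower (64.6% higher, against 51.6%).

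The second comparison set NCI-H358-R on drug against the same line off drug. The time off drug is not given, so a response to dosing and an effect of withdrawal cannot be told apart. On drug, ERK output genes, amino acid stress genes of the ATF4 programme and growth factor ligands were called lower as lists. DNA replication genes and the tested alveolar genes were called higher. DUSP6 fell from 192 ± 6.78 to 14.5 ± 2.08 CPM (−3.73 ± 0.10, adjusted p = 6.8e-14). ASNS, asparagine synthetase (ENSG00000070669.17, chromosome 7, 97852118 to 97872542), fell from 440 ± 3.6 to 35.3 ± 1.78 CPM (−3.64 ± 0.08, adjusted p = 1.5e-14). CCNE2, a cyclin of the G1/S transition (ENSG00000175305.18, chromosome 8, 94879770 to 94896678), rose from 5.52 ± 1.06 to 66.3 ± 9.49 CPM (3.58 ± 0.14, adjusted p = 3.2e-12). In all, 5431 genes were higher and 5403 lower, of which 2337 and 1963 changed at least 2-fold.

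Of 22 ERK output genes, 21 fell and 0 rose, with a median of −1.66 (adjusted p = 2.4e-33, and adjusted p = 0.021 with an estimated correlation). DUSP5 fell −4.67 ± 0.11, DUSP4 −4.02 ± 0.09, SPRY4 −3.13 ± 0.11 and ETV4 −1.64 ± 0.09. HRAS rose (0.91 ± 0.10). NRAS was not called (−0.19 ± 0.09, adjusted p = 0.074), but it was called without on-drug replicate 2 (−0.29, adjusted p = 0.0038), and with library size only its difference was 0.07. Of the 24 cascade members, 5 rose and 10 fell, with MAP2K1, which encodes MEK1, at −1.11 ± 0.08. The list was not called (adjusted p = 0.37), and its median of −0.16 became 0.09 with library size only, where 8 rose and 5 fell. Of 25 receptor tyrosine kinases, 11 rose and 8 fell (adjusted p = 0.42, not called). ERBB2 (1.73 ± 0.10) and FGFR3 (3.43 ± 0.14) rose, whereas MET (−1.83 ± 0.11), EGFR (−1.12 ± 0.13) and AXL (−0.54 ± 0.08) fell.

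Of 24 growth factor ligands, 15 fell and 7 rose (adjusted p = 3.3e-09, and adjusted p = 0.022 with an estimated correlation). AREG (ENSG00000109321.11, chromosome 4, 74445134 to 74455009), a ligand of the epidermal growth factor receptor, fell from 448 ± 27.9 to 16 ± 1.12 CPM (−4.81 ± 0.11), EREG fell −4.26 ± 0.09, VEGFA −3.55 ± 0.09 and FGF19 −7.44 ± 0.19. Of 25 integrin and laminin genes, 20 fell and 4 rose (adjusted p = 5.2e-19, and adjusted p = 0.15 with an estimated correlation), including LAMA3 (−4.58 ± 0.11) and ITGA6 (−3.65 ± 0.10). Secreted proteases and their inhibitors fell in 12 of 22 cases and rose in 6 (adjusted p = 0.0029, and adjusted p = 0.37 with an estimated correlation), MMP1 by −5.51 ± 0.21. Of 24 NF-kB and inflammatory genes, 11 fell and 4 rose (adjusted p = 0.01, and adjusted p = 0.2 with an estimated correlation).

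Of 23 ATF4 response genes, 22 fell and 1 rose, with a median of −2.12 (adjusted p = 6.6e-30, and adjusted p = 0.014 with an estimated correlation). CHAC1 fell −3.64 ± 0.11 and TRIB3 −2.97 ± 0.09. ER chaperone genes fell in 16 of 19 cases and rose in 2 (adjusted p = 0.00027, and adjusted p = 0.37 with an estimated correlation), and glycolysis and hypoxia genes fell in 19 of 28 and rose in 3 (21 and 4 adjusted over the list alone; adjusted p = 2.2e-06, and adjusted p = 0.3 with an estimated correlation). Fatty acid synthesis genes fell in 13 of 17 cases and rose in 1 (adjusted p = 0.02, and adjusted p = 0.5 with an estimated correlation), and 8 fell with library size only. Cholesterol synthesis genes fell in 13 of 21 and rose in 5 (adjusted p = 0.048, and adjusted p = 0.37 with an estimated correlation). That call was lost with library size only (adjusted p = 0.16), upper-quartile factors (adjusted p = 0.088) and the replicate block (adjusted p = 0.062). Of 35 ribosomal protein genes, 32 fell and 0 rose, with a median of −0.39 (adjusted p = 0.02, and adjusted p = 0.77 with an estimated correlation), and 9 fell with library size only and 17 with upper-quartile factors. Antigen presentation genes fell in 13 of 22 cases and rose in 2 (adjusted p = 0.025, and adjusted p = 0.37 with an estimated correlation), and immediate early genes fell in 9 of 17 and rose in 6 (adjusted p = 0.03, and adjusted p = 0.54 with an estimated correlation), the latter call lost with library size only (adjusted p = 0.066). Of 22 p53 targets, 9 fell and 7 rose, and 12 rose with library size only. Their median was 0.10, their mean −0.39, and the test called them lower (adjusted p = 0.025, and adjusted p = 0.37 with an estimated correlation). GDF15 fell −4.76 ± 0.14 and TP53INP1 rose 3.57 ± 0.15.

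Replication and mitotic genes parted. Of 30 replication and G1/S genes, 29 rose and 0 fell, with a median of 1.41 (adjusted p = 8.3e-22, and adjusted p = 0.016 with an estimated correlation). E2F2, a transcription factor of the G1/S programme, rose 3.67 ± 0.19. Of 30 mitotic genes, 6 rose and 11 fell and the list was not called (adjusted p = 0.81). Its median of −0.11 became 0.14 with library size only, where 13 rose and 6 fell, and 0.02 with upper-quartile factors, where 11 rose. FOXM1 rose (1.31 ± 0.08), BUB1 fell (−1.08 ± 0.10), and MKI67 was not called (0.32 ± 0.16, adjusted p = 0.088). CCND1, the cyclin D1 gene, fell −0.96 ± 0.09.

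Of 13 tested alveolar genes, 10 rose and 1 fell (adjusted p = 9.6e-05, and adjusted p = 0.032 with an estimated correlation). The list has 21 members. Its surfactant genes SFTPA1, SFTPA2, SFTPB, SFTPC and SFTPD were too low to test, with at most 33 counts each summed over all libraries. NKX2-1, the lung lineage transcription factor (ENSG00000136352.19, chromosome 14, 36516392 to 36521149), rose from 30.7 ± 1.35 to 134 ± 10.6 CPM (2.13 ± 0.09), and CLIC5 rose 4.46 ± 0.15. Of 27 epithelial genes, 13 rose and 8 fell (adjusted p = 0.025, and adjusted p = 0.58 with an estimated correlation), among them CDH1 (0.51 ± 0.10), CLDN3 (1.81 ± 0.12) and GRHL1 (3.15 ± 0.10). Of 23 mesenchymal genes, 10 rose and 9 fell and the list was not called (adjusted p = 0.82). Its median of 0.19 and mean of 0.44 differed in sign from the test. VIM (−1.31 ± 0.09), ZEB1 (−1.82 ± 0.16) and INHBA (−3.87 ± 0.10) fell, and TAGLN, an actin-binding protein gene, rose 2.90 ± 0.14.

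Markers of other cell types differed as well. All 9 tested fibroblast markers lay above their off-drug mean on drug, and 7 were called higher and 0 lower (adjusted p = 0.00023, and adjusted p = 0.038 with an estimated correlation). The list has 12 members. DCN, POSTN and MFAP5 were too low to test, with at most 20 counts each summed over all libraries. LUM, a matrix proteoglycan gene, rose from 2.05 ± 0.619 to 89.3 ± 18.9 CPM (5.43 ± 0.19), COL1A1 from 13.9 ± 1.31 to 43.9 ± 3.05 CPM (1.65 ± 0.10) and FBLN1 from 25.7 ± 1.26 to 59.3 ± 7.6 CPM (1.21 ± 0.11). COL1A2, which encodes the partner chain of COL1A1 and was singled out after its values were seen, was at 0.517 ± 0.1175 CPM on drug. Its change was 3.66, and 4.59 without off-drug replicate 2. Leukocyte markers fell in 3 of 5 cases (adjusted p = 0.0022, and adjusted p = 0.19 with an estimated correlation), with CD68 at −3.47 ± 0.10. Among the largest single changes, ZACN (6.47 ± 0.25), CLEC7A (5.51 ± 0.21) and MUC15 (6.06 ± 0.26) rose, and CALB2, the calretinin gene (−9.10 ± 0.18), PDE2A (−8.21 ± 0.17), NKD2 (−6.96 ± 0.17) and WNT7A (−6.18 ± 0.14) fell. ALPP, a placental alkaline phosphatase gene with close paralogs, rose 6.03 ± 0.16 and is uncertain to that extent.

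Of the 42 lists, 19 were called, 4 higher and 15 lower, 6 of them with an estimated correlation, and fry called 36. With library size only, 7784 genes were higher and 3585 lower (68.5% higher, against 50.1%), since the median of all genes then moved to 0.272 in this comparison, to 0.24 between on-drug and parental cells and to −0.031 between off-drug and parental cells. On log2(TPM + 1) values, 5321 were higher and 2995 lower (64%).

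The third comparison set resistant cells on drug against untreated parental cells. No parental cells on drug were measured, so differences between the lines and effects of the drug cannot be told apart here. On-drug cells carried more replication and mesenchymal transcripts than parental cells and fewer ERK output, ATF4 response and antigen presentation transcripts. With an estimated correlation the replication (adjusted p = 0.0067) and ATF4 (adjusted p = 0.017) calls held, and those of the mesenchymal (adjusted p = 0.13), ERK output (adjusted p = 0.11) and antigen presentation (adjusted p = 0.11) lists did not. CCNE2 rose from 2.42 ± 0.115 to 66.3 ± 9.49 CPM (4.78 ± 0.15, adjusted p = 4.7e-13). DUSP6 fell from 158 ± 1.7 to 14.5 ± 2.08 CPM (−3.45 ± 0.10, adjusted p = 2.3e-13). In all, 5777 genes were higher and 5690 lower, of which 2317 and 2407 changed at least 2-fold.

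Of 22 ERK output genes, 17 fell and 3 rose (17 and 4 adjusted over the list alone), with a median of −1.17 (adjusted p = 5.2e-12, and adjusted p = 0.11 with an estimated correlation). SPRY4 fell −1.02 ± 0.10, ETV4 −1.15 ± 0.09 and DUSP4 −3.28 ± 0.08. CCND1 was not called (0.21 ± 0.09, adjusted p = 0.05), but it was called without parental replicate 2 (0.29, adjusted p = 0.016) and without on-drug replicate 2 (0.27, adjusted p = 0.013). HRAS rose (0.39 ± 0.09). NRAS was not called (−0.21 ± 0.09, adjusted p = 0.054) and was called without on-drug replicate 2 (−0.32, adjusted p = 0.0018), while library size only gave 0.02. Of the 24 cascade members, 8 rose and 7 fell (8 and 6 adjusted over the list alone), or 13 rose with library size only, and the list was not called (adjusted p = 0.63). Of 25 receptor tyrosine kinases, 14 rose and 8 fell (adjusted p = 0.055, not called). AXL (4.19 ± 0.11) and FGFR1 (3.64 ± 0.14) rose, MET fell (−1.19 ± 0.11), and EGFR was not called (0.24 ± 0.13, adjusted p = 0.11). Of 24 growth factor ligands, 11 fell and 9 rose (11 and 10 adjusted over the list alone; adjusted p = 1e-06, and adjusted p = 0.069 with an estimated correlation). Their median of −0.20 became 0.02 with library size only. AREG fell −5.19 ± 0.11 and FGF19 −7.46 ± 0.19.

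Of 30 replication and G1/S genes, 29 rose and 0 fell, with a median of 2.41 (adjusted p = 1.4e-44, and adjusted p = 0.0067 with an estimated correlation). Of 30 mitotic genes, 26 rose and 2 fell (adjusted p = 5.5e-07, and adjusted p = 0.11 with an estimated correlation), with FOXM1 at 2.38 ± 0.09 and MKI67 at 1.87 ± 0.17. Histone genes rose in 8 of 9 cases (adjusted p = 0.008, and adjusted p = 0.19 with an estimated correlation). Of 23 mesenchymal genes, 18 rose and 5 fell (adjusted p = 1.7e-07, and adjusted p = 0.13 with an estimated correlation). SPARC rose 6.89 ± 0.11, VIM 1.82 ± 0.09, ZEB1 1.34 ± 0.19 and the N-cadherin gene CDH2 3.34 ± 0.13. YAP/TEAD targets rose in 16 of 20 cases and fell in 1 (adjusted p = 5.1e-10, and adjusted p = 0.11 with an estimated correlation), and TGF-beta response genes rose in 14 of 19 and fell in 4 (adjusted p = 0.00034, and adjusted p = 0.13 with an estimated correlation). Alveolar genes rose in 7 of 13 cases and fell in 3 (adjusted p = 0.026, and adjusted p = 0.13 with an estimated correlation), NKX2-1 by 1.04 ± 0.08. All 9 tested fibroblast markers were called higher (adjusted p = 3.3e-05, and adjusted p = 0.069 with an estimated correlation). DCN, POSTN and MFAP5, also among the 12 members of that list, were too low to test. COL3A1, singled out after its values were seen, was at 4.68 ± 0.417 CPM on drug and had 0 counts in each parental and off-drug library, where 3 counts would be at most 0.123 CPM. It passed the filter only through the on-drug libraries, so only a rise could be seen for it.

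Of 23 ATF4 response genes, 21 fell and 1 rose (21 and 2 adjusted over the list alone; adjusted p = 2.5e-23, and adjusted p = 0.017 with an estimated correlation), with ASNS at −3.07 ± 0.08. Integrin and laminin genes fell in 18 of 25 cases and rose in 3 (adjusted p = 6.2e-11, and adjusted p = 0.19 with an estimated correlation), and antigen presentation genes fell in 18 of 22 and rose in 1 (adjusted p = 3.3e-05, and adjusted p = 0.11 with an estimated correlation). HLA-B (−1.80 ± 0.10) shares reads with other HLA genes and is uncertain to that extent, and B2M fell −1.45 ± 0.11. NRF2 targets fell in 17 of 24 cases and rose in 2 (adjusted p = 3.3e-05, and adjusted p = 0.11 with an estimated correlation), p53 targets fell in 13 of 22 and rose in 6 (adjusted p = 0.00023, and adjusted p = 0.11 with an estimated correlation), and squamous genes fell in 8 of 13 and rose in 2 (adjusted p = 0.0014, and adjusted p = 0.19 with an estimated correlation). Glycolysis and hypoxia genes fell in 17 of 28 cases and rose in 3 (adjusted p = 9.6e-06, and adjusted p = 0.23 with an estimated correlation), fatty acid synthesis genes fell in 11 of 17 and rose in 3 (adjusted p = 0.0015, and adjusted p = 0.28 with an estimated correlation), and ER chaperone genes fell in 15 of 19 and rose in 2 (adjusted p = 0.0058, and adjusted p = 0.36 with an estimated correlation). Of 29 nuclear respiratory chain genes 24 fell and 1 rose (2 rose adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.64 with an estimated correlation), and 12 fell with library size only. Of 35 ribosomal protein genes 33 fell and 0 rose (adjusted p = 0.00082, and adjusted p = 0.64 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 21 cases and rose in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.035, and adjusted p = 0.26 with an estimated correlation), a call lost with library size only (adjusted p = 0.095). Leukocyte markers fell in 3 of 5 cases and rose in 1 (adjusted p = 0.036, and adjusted p = 0.23 with an estimated correlation), a call lost without off-drug replicate 2 (adjusted p = 0.066), where 6 members were tested, 1 rose and 4 fell.

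Epithelial genes were not called in this comparison, with 10 higher and 12 lower (adjusted p = 0.49), and their median of −0.22 became 0 with library size only. EPCAM fell −1.68 ± 0.08. CDH1 was called higher (0.30 ± 0.10, adjusted p = 0.017), a call lost without on-drug replicate 1 (0.20, adjusted p = 0.12) and without on-drug replicate 3 (0.25, adjusted p = 0.08). The largest rises included BPIFB4 (10.50 ± 0.18), HAPLN1, a hyaluronan link protein gene (10.39 ± 0.25), and ALPP (9.31 ± 0.22), whose reads may be shared with paralogs. CYP2F1, a lung cytochrome P450, had 0 counts in the parental libraries and 17.2 ± 2.47 CPM on drug, at least 157-fold higher against a floor of 3 counts per library. NKD2 (−8.64 ± 0.16), TCIM (−7.80 ± 0.14) and CALB2 (−7.53 ± 0.19) were among the largest falls.

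Of the 42 lists, 23 were called, 8 higher and 15 lower, 2 of them with an estimated correlation, and fry called 38. With library size only, 7597 genes were higher and 4225 lower (64.3% higher, against 50.4%), and on log2(TPM + 1) values 6502 were higher and 2828 lower (69.7%).

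**Figure D2:**
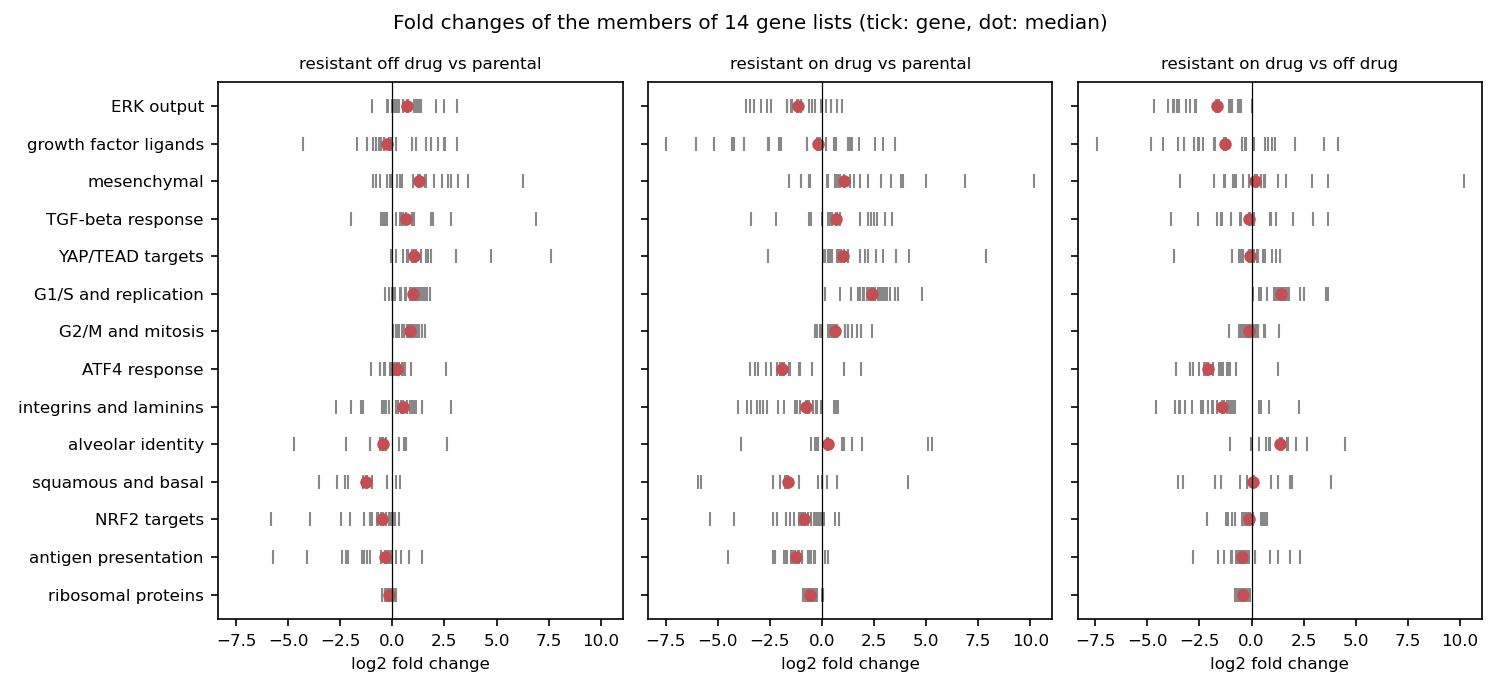
Fitted log2 fold changes (horizontal axes) of the tested members of 14 gene lists in the 3 comparisons. Each tick is 1 gene and each dot the list's median, which for ERK output was 0.72 off drug against parental cells, −1.17 on drug against parental cells and −1.66 on drug against off drug.

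How far the differences of off-drug cells from parental cells were also present on drug was read from the overlap of calls. Of the 4913 genes higher off drug than in parental cells, 2801 (57%) were also higher on drug than in parental cells, 1176 were not called there and 936 (19.1%) were lower. Of the 4602 lower genes, 2706 (58.8%) were also lower on drug and 655 (14.2%) were higher. Independent lists of these sizes would share 1640 higher and 1513 lower genes. In 100 simulations of unchanged groups that share the parental libraries, the overlap was at most 1 and 2. Few genes are called in such groups, so these simulations do not measure what sharing adds where many genes change. Part of the excess may come from the shared parental libraries, which were too few to split. Across genes, which are not independent replicates, the changes of the off-drug and on-drug states against parental cells correlated at r = 0.55 (Spearman 0.426). Unchanged groups gave 0.483 to 0.553 (0.446 to 0.479). A shared group gives such correlations from noise of any size, so that range cannot judge r where changes are larger than noise. The covariance, which grows with the size of the changes, was 0.887 against a simulated mean of 0.038 (0.035 to 0.042). Noise as simulated, with each gene at its mean over all 9 libraries, therefore made up little of it. Noise at the lower parental level of some genes, and a shift common to all parental libraries, were not simulated. Between the off-drug change and the change on against off drug, r was −0.243 (Spearman −0.277) against a simulated −0.553 to −0.482 (−0.486 to −0.448). The same limit holds for that range. The covariance was −0.337 against −0.043 to −0.034. Of the 4913 higher genes, 2380 (48.4%) were lower on drug than off drug and 1011 were higher. Of the 4602 lower genes, 2084 (45.3%) were higher on drug than off drug and 1045 were lower. Both comparisons use the off-drug libraries, which favours such opposite signs, and these counts were not set against simulated ones. The time off drug is not given, so the off-drug state need not be the starting point. AXL, SPARC and VIM were above parental levels in both resistant states, whereas SPRY4 and DUSP4 lay below them on drug.

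Groups did not overlap for 61.85% of the tested genes between off-drug and parental cells, 69.02% between on-drug and parental cells and 67.61% between on-drug and off-drug cells, where chance gives 10% for 3 libraries against 3.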

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

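Of the alternatives reported here, only the counts of lists without off-drug replicate 2 (17 off drug against parental cells, 19 on against off drug) were chosen after the data were seen. Counts of called genes stayed within 1.5 times their value under RLE and upper-quartile factors, both count filters, DESeq2, voom, fits of only the groups compared, and each library left out. Library size only moved 1 of them, the genes lower on than off drug, to 3585. Limma on TPM values moved all counts of lower genes on each of the 3 TPM settings. The counts stayed low with no filter on TPM, so that filter is not the cause. Limma voom on counts kept lower genes at 4533, 5748 and 5460 (off drug against parental, on drug against parental, on against off drug). That argues against limma as such. On log2(TPM + 1) with the filter the median of all genes moved to 0.13, 0.273 and 0.157 in that order, against 0.001, 0.016 and 0.016. Limma trend was not run on counts, so that test and the scale were not separated. In the order log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) with no filter, lower genes numbered 2529, 2531 and 2671 off drug against parental cells, 2828, 2802 and 3162 on drug against parental cells and 2995, 2975 and 3000 on against off drug. Those lower by at least 2-fold numbered 526, 822 and 564, then 875, 1118 and 922, then 895, 1115 and 917. Genes higher by at least 2-fold numbered 731 and 751 off drug against parental cells and 1305 and 1410 on against off drug, on log2(TPM + 1) with and without the filter. That pseudocount shrinks the fold changes of low genes by construction. With an estimated correlation camera called 0 lists (9 at an unadjusted p under 0.05), 2 and 6 in the order off drug against parental, on drug against parental and on against off drug, and fry called 33, 38 and 36. With no filter the correlation of the off-drug change with the change on against off drug was −0.382, against −0.243. Leaving out each library gave 4435 to 4878 higher and 4042 to 4378 lower genes off drug against parental cells, 5267 to 5675 and 5358 to 5644 on drug against parental cells, and 4980 to 5172 and 4945 to 5180 on against off drug. For named genes, 3344 of 3398 values under an alternative kept their direction and side of the threshold, 15 lost the call, 29 gained one and 10 changed sign, all of NRAS. NRAS was not called in any comparison and changed sign as follows: off drug against parental cells to 0.06 on each TPM scale and to 0.01 without parental replicate 1 or off-drug replicate 2 (−0.05 to 0.01 over all libraries left out), on drug against parental cells to 0.02 with library size only and 0.01 on each TPM scale, and on against off drug to 0.07 with library size only. In simulated counts 56.7 to 68.7% of genes changed 1.5-fold were recovered, against 88.1 to 92.5% at 2-fold, and the parts of depth and replicate number in this were not tested.

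With the replicate block, 4906 genes were higher and 4537 lower off drug against parental cells, 5768 and 5649 on drug against parental cells, and 5383 and 5375 on against off drug. Lists called numbered 21, 23 and 18 in that order. The RAS-RAF-MEK-ERK cascade (adjusted p = 0.043, against 0.057) and p53 targets (0.04, against 0.062) gained a call off drug against parental cells, and cholesterol synthesis (0.062, against 0.048) lost its call on against off drug. The labels do not say that a number marks a shared day. Same-numbered libraries of different groups deviated together at correlations of −0.25 to 0.26, over 0.1 in 4 of 9 pairs, and 3 of 9 libraries correlated best with their own number.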

Other observations

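The tests of carry-over between libraries, of library scaling and of S phase, the comparison of off-drug replicates 1 and 3, and the number of lists without off-drug replicate 2 were chosen only after the result was seen.

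Drug transporters and detoxifying enzymes moved apart between off-drug and on-drug cells. Of 18 tested, 8 rose and 7 fell on against off drug, and the list was not called (camera adjusted p = 0.37). ABCG2, an efflux transporter, fell from 13.2 ± 1.74 to 1.82 ± 0.129 CPM (−2.85 ± 0.14), whereas ALDH1A1, an aldehyde dehydrogenase, rose from 0.408 ± 0.0473 to 8.64 ± 1.34 CPM (4.39 ± 0.26), and ABCC5 (2.06 ± 0.09) and MGST1 (1.52 ± 0.08) rose. Of 15 BCL2 family genes, 8 fell and 5 rose (8 and 6 adjusted over the list alone; adjusted p = 0.067). BCL2A1, an antiapoptotic member, fell −3.56 ± 0.20, the proapoptotic BMF rose 2.00 ± 0.13, and PMAIP1 (−1.77 ± 0.10) and BIK (−1.76 ± 0.12), also proapoptotic, fell. Interferon-stimulated genes went both ways, 11 up and 12 down of 31 (adjusted p = 0.74), with MX1 (2.22 ± 0.13) and IFI6 (2.05 ± 0.12) higher and OASL (−2.87 ± 0.09) lower. Of 15 Notch pathway genes 5 rose and 7 fell (adjusted p = 0.27), among them the ligand gene JAG1 (−2.27 ± 0.09) and HEY1 (−1.46 ± 0.08).

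Off-drug replicate 2 held CP, CAPS and SPANXA2, the 3 genes in which the pattern was seen, at a median of 4.58% of their parental level. Another 64 genes, 4- to 16-fold higher in parental cells than in the mean of off-drug replicates 1 and 3, lay above that mean in replicate 2 by a median of 4.41% of the distance to the parental mean (quartiles 3.27 and 6.22%), and replicates 1 and 3 differed from each other by a median of 0.177% of it (quartiles −1.67 and 2.26%). Carry-over from every library is argued against by 3 genes found almost only on drug, whose median share in replicate 2 was 0.74%. The same rule, with genes chosen anew for each library, gave 1.2 and 1% in off-drug replicates 1 and 3. A small amount of parental RNA or cells may have entered this library, and neither which of them nor a part of the resistant cells in a parental-like state was tested. Without it, 17 lists were called off drug against parental cells.

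Replication genes rose on against off drug and mitotic genes as a list did not, with a difference of 1.52 between the list medians. A single scaling factor per library moves both lists alike, and after removal of the trend with GC content and length it was 1.58. That trend held 0.38% of the variance of fold changes and moved no gene by more than 0.53, so it is too small to make the difference. Per library, the difference was at least −0.05 on drug and at most −1.19 off drug. A larger share of cells in S phase could raise replication genes, but the histone genes that would rise with it had a median of 0.38 and were not called (adjusted p = 0.34), and poly(A) selection measures them poorly, so this explanation and a change in transcription per cell cannot be told apart.

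With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Refitted on 6 libraries, the real split called 9337 genes off drug against parental cells, 11106 on drug against parental cells and 10981 on against off drug, each as the only 1 of 10 to reach its number. The highest count from any other split was 0 by edgeR at an adjusted p under 0.05, with up to 249, 177 and 172 genes at an unadjusted p under 0.05. Every other split puts libraries of both states in each group, so differences between states widen its spread and few calls are expected. That 0 therefore does not measure false calls.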
